A study of Drosophila melanogaster with 15 samples.

How the data were processed

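The study compared 5 tissues of Drosophila melanogaster with whole animals at about 18 hours before pupariation on 15 2-colour arrays, 3 per tissue. Per the labels' protocols, the larvae were of the Canton S strain, the RNA was amplified by in vitro transcription, each array held 1 tissue sample in Cy5 and the whole animal reference in Cy3, the 3 samples of a tissue were independent, and no dyes were swapped. Groups and replicate numbers were taken from the sample titles. The scanner, the background correction, the normalization and the reason for empty cells are not given in the sources used here, nor is whether the reference was 1 pool of RNA. The p-values measure the spread between samples of a tissue, and the reference's own spread is not in them.

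The values deposited by the authors were log2 ratios, 1 column per array. That scale was read from the values. On each array 100% of them were the log2 of a whole number of steps of 0.001 minus 1 constant per array. The constants were -0.03 to -0.586 log2, so the stepped ratios stood divided by factors of 0.979 to 0.666. Between 851 and 1078 pairs of values per array differed by exactly 1 and 398 to 516 by log2 of 3, against 5 to 14 by the natural logarithm of 2 and 5 to 13 by an arbitrary number, to the precision of the file. Steps of the ratio survived, so a correction that varies with intensity is not visible in the deposited values. Array medians as deposited lay between -0.137 and 0.0816 log2. The direction, tissue over whole animal, was read from the dyes and channels in the labels and checked with marker lists. All 8 salivary gland genes, 42 of 45 midgut enzyme genes and 18 of 23 muscle genes were highest in their own tissue, as were 19 of 40 neuron and glia genes, 22 of 38 cuticle genes and 23 of 40 disc genes. Lowest in their own tissue were 6 neuron and glia genes, 1 cuticle gene and 4 disc genes. In the salivary gland, midgut enzyme and muscle lists 0 genes were lowest there, so these lists bear most on the direction.

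The table held 20000 rows, of which 14051 had a value on at least 1 array and 5949 had none. Rows were named through an annotation table of the array and current gene records. Among measured rows, 10817 had 1 gene, 227 had several and 3007 had none, and 10813 matched a current record, with 0 symbols changed and 4 kept as annotated. Rows of 1 gene were averaged, which gave 13128 features with 9894 named genes, and rows with several genes or none were kept as unnamed features. Of 793 genes with more than 1 row, 326 had rows more than log2 1 apart in at least 1 tissue, and among genes named in the text Ggamma30A, Hr39, Hsp26 and Pepck1 were of that kind. No genome build is named in the sources used here, so no coordinates are given.

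Each array was centred on its median. Every feature was fitted with limma (version 3.58.1 in R 4.3.3) over all 15 arrays with 1 mean per tissue, and the variances were moderated by empirical Bayes (prior degrees of freedom 5.965, prior SD 0.338 log2). A feature entered a comparison where it was measured on at least 2 of 3 arrays in each tissue needed. Comparisons were each tissue against whole animal (the mean ratio against 0), each tissue against the mean of the other 4, all 10 pairs, an F test over the 5 tissues, and genes highest in 1 tissue, which had to be at least log2 1 above each of the other 4 with each difference past the test. Adjusted p-values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05. Tables and plots were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

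A set of 18 gene lists was tested with camera on the moderated statistics at a preset correlation of 0.01 where at least 4 members were measured, adjusted over lists and tissues. The lists were salivary gland products and regulators (8 genes found among measured rows annotated with 1 gene), midgut digestive enzymes (45), neuron and glia genes (42), muscle genes (24), cuticle and epidermis genes (42), imaginal disc patterning genes (44), fat body genes (15), hemocyte genes (17), testis and germline genes (13), DNA replication and mitosis genes (49), cytosolic ribosomal proteins (32), mitochondrial respiratory chain and ATP synthase (67), translocon, signal peptidase and COP vesicle genes (37, called secretory pathway genes in the text), V-ATPase subunits (24), ecdysone pathway genes (37), Hox genes (2), heat shock proteins and cytosolic chaperones (13) and antimicrobial peptides and pathogen recognition (11, called immune genes). Camera with an estimated correlation and fry were run on the 4540 features measured on all arrays.

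The groups, the comparisons, the lists, the rule for named genes and most of the alternatives were fixed before the data were examined. Among features with exactly 1 symbol, the rule took, per tissue against whole animal, the 8 highest and 5 lowest past the test with the same sign on all measured arrays. Against the other 4 tissues it took the 8 highest and 4 lowest past the test with every array of the tissue above (or below) every array of the others, up to 4 members past the test per list and tissue with the largest differences, and the 3 genes with the widest margin among genes highest in 1 tissue. It also took a fixed set of ecdysone regulators (EcR, usp, br, Eip74EF, Eip75B, Hr3, Hr39 and ftz-f1) and the Hox genes where measured. Genes named outside this rule are said to be so.

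The alternatives were values as deposited, arrays scaled to the same median absolute deviation, features measured on all 15 arrays only, no filter on missing values, each row tested on its own, array weights, a robust variance model, only the arrays of the groups compared, the replicate number as a block, other fold minimums, fry, camera with an estimated correlation, and leaving out each array in turn. Added after seeing the data were centring within 4 classes of rows by the number of arrays that measured them, ratios under 20 steps of 0.001 set to 20 steps, 12 arrays without replicate 3 of epidermis, salivary gland and midgut, and named genes only. The scripts were tested on simulated data with 8432 genes and the spread of the real arrays. Of 100 genes changed by log2 1, 57 to 69 were recovered against the other 4 tissues and 71 to 80 against whole animal. Of 100 changed by log2 2, 98 to 100 were recovered against the other 4 and 99 to 100 against whole animal, and the F test recovered 19 to 30 of 100 at log2 1 and 96 to 98 at log2 2. False calls made up 3.09% to 8.29% of all calls. The simulated noise was independent between genes and between arrays, without differences between dim and bright rows, so these numbers need not hold for the real arrays. In the simulated test of the lists, 2 were called, the 1 list that had been shifted and 1 that had not.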

Results

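Transcript levels were measured in 5 dissected tissues of Drosophila melanogaster larvae of the Canton S strain, a wild-type stock, at about 18 hours before puparium formation. The tissues were epidermis with attached muscle, salivary gland, wing imaginal disc, midgut and central nervous system, each on 3 arrays of independent samples, which made 15 arrays. Every array set 1 tissue against RNA of whole animals of the same stage, so each value was a log2 ratio of tissue over whole animal. Arrays measured between 7747 rows (epidermis replicate 3) and 13505 rows (epidermis replicate 2) out of 14051 rows with any value. Correlations between arrays of 1 tissue, across 4540 features measured on all arrays, ran from 0.686 to 0.847 in epidermis and from 0.883 to 0.916 in the central nervous system. The median SD between arrays was 0.373 log2 in epidermis, 0.327 in salivary gland, 0.288 in wing disc, 0.266 in midgut and 0.26 in the central nervous system. The number of arrays limits the precision of every value.

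The comparisons asked which genes each tissue held above or below the others, and above or below the whole animal, shortly before the onset of metamorphosis. Differences from the mean of the other 4 tissues are given first, since the reference and any dye effect common to all arrays cancel in them. That mean includes the tissue in which a gene or list was highest, so a value below it can come from a high level in 1 other tissue. Likewise, a value above it can come from low levels in some of the other tissues. Each list call was therefore also tested between pairs of tissues, with camera at the preset correlation and adjustment over all pairs and lists. Ratios to whole animal leave out the reference's own spread and hold any gene-specific dye effect, because the tissue was always in Cy5. Their balance of higher and lower calls also depends on the centring of each array on its median over all rows. Rows measured on all 15 arrays lay below that median on every array, which lowers the share of higher calls among them. Errors are standard errors of the limma fit, adjusted p-values are Benjamini-Hochberg values of that fit, and values rest on 3 arrays of the named tissue unless another n is given. Of 8432 features tested in all tissues, 3750 (44.5%) differed among the 5 tissues. Gene lists were tested with camera at a preset correlation between genes of 0.01, and 37 of 85 tests against the other 4 tissues passed. With an estimated correlation, 5 of these 85 tests passed, namely salivary gland genes and secretory pathway genes in the salivary gland, digestive enzymes in the midgut, cuticle genes in epidermis and DNA replication genes in the wing disc. Camera with an estimated correlation used only the 4540 features measured on all arrays. A call lost there can thus come from the smaller set of features as well as from the correlation. Against whole animal, 48 of 85 tests passed camera at the preset correlation and 0 passed with an estimated correlation (23 had an unadjusted p under 0.05, and 65 passed limma's rotation test fry). Camera at the preset correlation also called a median of 29 and up to 39 of the 85 tests when the 15 arrays were regrouped at random, so the number of list members past the limma test is given for each list.

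**Figure D1:**
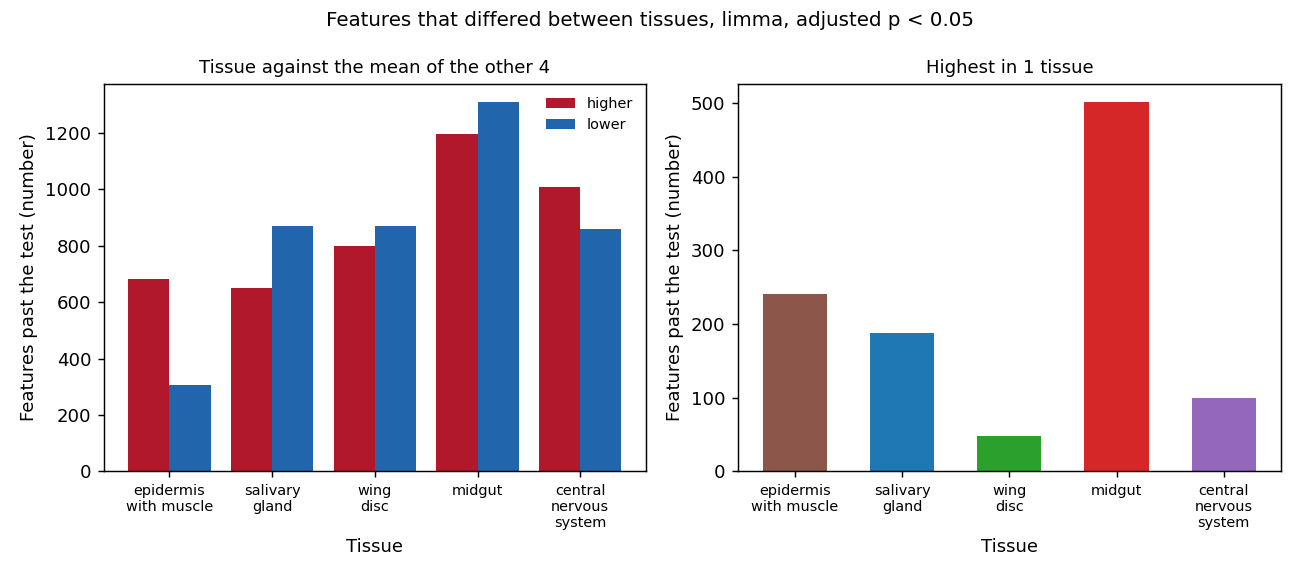
The left panel shows, for each tissue, the number of features higher (red bars) and lower (blue bars) than the mean of the other 4 tissues at the limma threshold, and the right panel the number of features highest in 1 tissue. Midgut had the most in both, with 1196 higher, 1310 lower and 501 highest there, and wing disc the fewest highest in 1 tissue, with 48.

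Epidermis with muscle held many muscle and some cuticle transcripts above the other 4 tissues. The projectin gene bt, which encodes a giant protein of the sarcomere, was higher by log2 5.43 (SE 0.329, adjusted p = 8.43e-09), the muscle LIM protein gene Mlp84B by 4.85 (SE 0.396), and the myosin light chain genes Mlc2 and Mlc1 by 4.84 (SE 0.342) on n = 2 arrays and 3.74 (SE 0.367). Of 21 measured muscle genes, 17 passed the test, each of them higher, and 4 did not (camera adjusted p = 1.23e-29; adjusted p = 0.0575 with an estimated correlation). Adjusted over the list alone, 19 muscle genes were higher. Among 23 cuticle and epidermis genes, 11 passed, each higher, and 12 did not (camera adjusted p = 2.26e-15), with 15 higher when adjusted over the list alone. They included the cuticle protein genes Cpr49Ac at 4.54 (SE 0.376), Pcp at 4.38 (SE 0.295) and Lcp9 at 3.71 (SE 0.38), and Ddc, the dopa decarboxylase of cuticle tanning, at 3.83 (SE 0.401). The largest difference was that of CG5171, a gene with no name, at 6.31 (SE 0.26, adjusted p = 3.07e-10), followed by yellow-d2 of the yellow family at 6.25 (SE 0.352).

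Among single genes, ImpL2, whose product binds insulin-like peptides, was higher by log2 2.22 (SE 0.226), and Cyp18a1, which inactivates 20-hydroxyecdysone, by 1.86 (SE 0.207). The imaginal disc growth factors Idgf2 and Idgf3 were higher by 2.17 (SE 0.218) and 1.66 (SE 0.179). Relative to whole animal, Idgf3 lay at -0.68 in epidermis, -0.44 in salivary gland and -0.73 in central nervous system. Its difference came from wing disc (-4.175) and midgut (-4.025). Idgf2 and Idgf3 belonged to the fat body list. Of its 14 members 4 passed the test, each higher, and 10 did not, with 5 higher when adjusted over the list alone. The camera call for that list (adjusted p = 0.0192; adjusted p = 0.185 with an estimated correlation) was lost without epidermis replicate 1 (adjusted p = 0.0784), without epidermis replicate 2 (0.104) and when arrays were scaled to a common spread (0.549). By pairs, fat body genes were higher in epidermis than in wing disc (adjusted p = 6.36e-07) and central nervous system (0.0325), and did not pass against salivary gland (0.549) and midgut (0.111). Rbp9, an RNA-binding protein gene of the neuron and glia list, was higher in epidermis by 2.37 (SE 0.274), although that list as a whole had only 2 members higher and 1 lower among 26 (camera adjusted p = 0.814; median -0.08, mean 0.04). Relative to the mean of the other 4 tissues, which includes midgut, 21 of 39 digestive enzyme genes passed the test, each lower, 31 when adjusted over the list alone (camera adjusted p = 2.27e-12; adjusted p = 0.0994 with an estimated correlation). By pairs, digestive enzyme genes were lower in epidermis than in midgut (adjusted p = 1.06e-67), and did not pass against salivary gland (0.0572), wing disc (0.852) and central nervous system (0.852). Relative to a mean that includes the salivary gland, sage, a transcription factor gene of the gland, was at -1.71 (SE 0.21), 4 of 8 salivary gland genes were lower and 4 did not pass (6 lower when adjusted over the list alone; camera adjusted p = 7.00e-06; adjusted p = 0.0948 with an estimated correlation). By pairs, salivary gland genes were lower in epidermis than in salivary gland (adjusted p = 3.47e-49), and did not pass against wing disc (0.639), midgut (0.892) and central nervous system (0.735).

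In all, 990 of 8432 features differed between epidermis and the other 4 tissues, 684 higher (69.1%) and 306 lower. Without epidermis replicate 3, which measured the fewest rows, the count was 594, with 495 higher and 99 lower (83.3% higher). With arrays centred within classes of dim and bright rows the share that was higher was 58.5%. Against whole animal, 2707 of 11027 features passed, 1334 higher and 1373 lower, and the share that was higher ran from 35.6% without epidermis replicate 2 and 38.2% over features measured on all 15 arrays to 51.2% with a replicate block. At a minimum difference of log2 1, 530 were higher and 839 lower. Without that minimum, the count was 1652 without epidermis replicate 1 and 1596 without epidermis replicate 2. Hsp68, a heat-inducible chaperone gene, stood 3.96 (SE 0.231) above whole animal, and the trypsin gene zetaTry -5.44 (SE 0.665) relative to it.

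**Figure D2:**
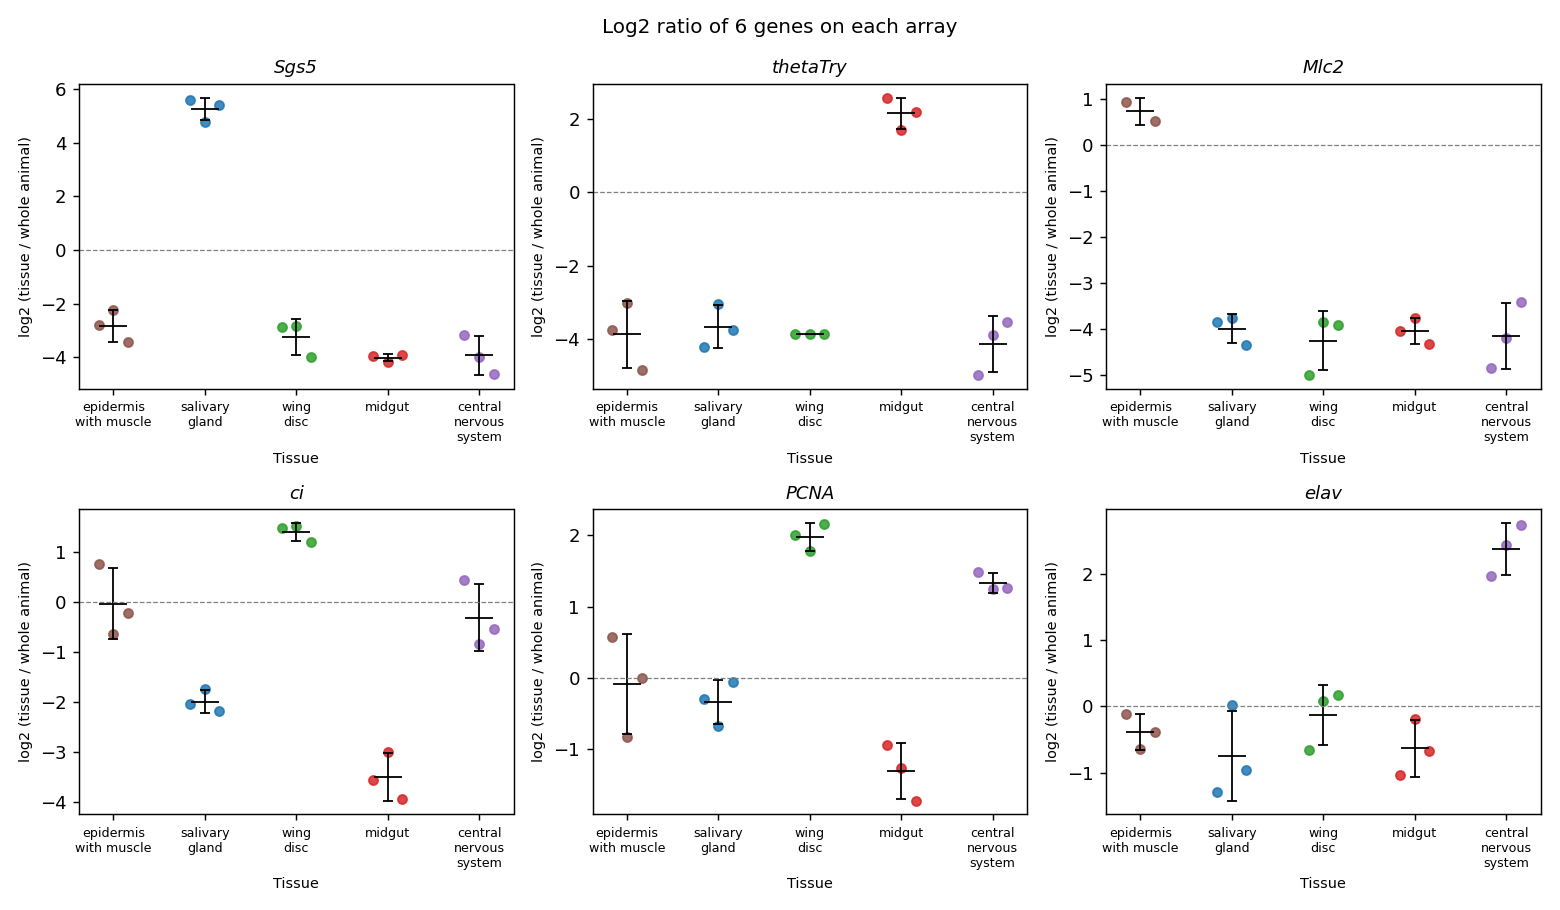
Each panel shows the log2 ratio of tissue over whole animal of 1 gene on each array (points), with the mean per tissue (dash) and the SD between arrays (bar), for Sgs5, thetaTry, Mlc2, ci, PCNA and elav. Sgs5 was highest on the 3 salivary gland arrays, thetaTry on the 3 midgut arrays and Mlc2 on the epidermis arrays, where n = 2, while PCNA was higher in wing disc and central nervous system.

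The salivary gland, which at this stage makes the glue that later fixes the animal to its substrate, held glue and many secretory pathway transcripts above the other 4 tissues. Eig71Ee, an ecdysone-induced gene of the gland, was higher by log2 8.79 (SE 0.327, adjusted p = 3.26e-11), and the glue protein genes Sgs5 and Sgs1 by 8.77 (SE 0.312, adjusted p = 3.26e-11) and 6.23 (SE 0.532). The gland transcription factor gene sage was higher by 5.50 (SE 0.21). Of 8 measured salivary gland genes, 7 passed the test, each higher, and 1 did not (camera adjusted p = 1.33e-58), and 8 were higher when adjusted over the list alone. The adjacent glue genes Sgs5 and Sgs5bis are similar in sequence, so their separate values are uncertain. CG9040, CG12715 and CG7606, genes with no name, were higher by 7.86 (SE 0.30), 6.98 (SE 0.383) and 6.94 (SE 0.369).

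Camera also called secretory pathway genes higher in the gland. Of 35 measured genes for the translocon, signal peptidase and COP vesicles, 25 passed the test, each higher, and 10 did not (camera adjusted p = 1.02e-26), with 30 higher when adjusted over the list alone. They included the signal peptidase genes Spase25 at log2 3.15 (SE 0.201, adjusted p = 1.85e-08), Spase22-23 at 2.66 (SE 0.168) and twr at 2.50 (SE 0.218), and TRAM, a membrane protein gene of the translocation channel, at 2.62 (SE 0.337). Some fat body transcripts were also higher on the gland arrays than in the other 4 tissues. Lsp2, a storage protein gene of the fat body, was higher by 3.85 (SE 0.331), Fbp2 by 2.91 (SE 0.305) and Fbp1, a receptor gene for storage proteins, by 2.37 (SE 0.372). Lsp2 lay at -0.03 (SD 0.503, n = 3) log2 relative to whole animal in the gland and at -2.41 to -4.58 in the other tissues, whereas apolpp, which encodes the main lipid carrier of the blood and is made in fat body, lay at -2.71 (SD 0.704, n = 3) in the gland. Of 14 fat body genes, 6 were higher, 1 was lower and 7 did not pass (camera adjusted p = 0.000242; adjusted p = 0.132 with an estimated correlation), and adjusted over the list alone 8 were higher and 2 lower. By pairs, fat body genes were higher in salivary gland than in wing disc (adjusted p = 3.51e-07), midgut (0.0133) and central nervous system (0.00371), and did not pass against epidermis (0.549). The lower member was CtsL1, a cathepsin gene named after its value was seen, at -1.19.

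Some DNA replication and mitosis genes lay below the mean of the other 4 tissues in the gland. Of 38 DNA replication and mitosis genes, 17 passed the test, each lower, and 21 did not (camera adjusted p = 2.99e-05; adjusted p = 0.273 with an estimated correlation). Adjusted over the list alone, 19 were lower and 1 was higher. By pairs, DNA replication genes were lower in salivary gland than in wing disc (adjusted p = 1.21e-16) and central nervous system (4.08e-09), and did not pass against epidermis (0.629) and midgut (0.215). The condensin gene SMC2 was lower at -1.82 (SE 0.233), the replicative helicase gene Mcm6 at -1.43 (SE 0.189) and fzy, an activator of the anaphase-promoting complex, at -1.40 (SE 0.263). Relative to a mean that includes midgut, digestive enzyme genes had 14 of 39 past the test, each lower, 15 when adjusted over the list alone (camera adjusted p = 0.000741; adjusted p = 0.376 with an estimated correlation). By pairs, digestive enzyme genes were lower in salivary gland than in midgut (adjusted p = 4.36e-67), and did not pass against epidermis (0.0572), wing disc (0.212) and central nervous system (0.0572). Strn-Mlck, a myosin light chain kinase gene of the muscle list, was higher at 2.68 (SE 0.212), although of 21 genes in that list 1 was higher, 3 were lower and 17 did not pass. The camera adjusted p of that list in the gland was 0.674 (median -0.29, mean -0.27; 2 higher and 3 lower adjusted over the list alone). The nuclear receptor gene Hr78 was higher at 1.69 (SE 0.208). In all, 1521 features differed from the other 4 tissues, 651 higher (42.8%) and 870 lower. That balance turned to 433 higher and 325 lower at a minimum difference of log2 1. Without salivary gland replicate 3 it turned too, with 600 of the 1164 calls higher. The count was 825 without salivary gland replicate 1, and centring within classes of dim and bright rows made 53.1% of calls higher.

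Against whole animal, 3979 of 11232 features passed in the salivary gland, 1893 higher and 2086 lower. Over features measured on all 15 arrays the numbers were 540 higher and 1467 lower, with 26.9% higher against 47.6%. At a minimum difference of log2 1 and over the tested features, 581 were higher and 1050 lower. Without that minimum, 2150 passed without salivary gland replicate 3. Sgs5 stood 5.27 (SE 0.279, adjusted p = 6.69e-09) and Eig71Ee 5.15 (SE 0.293) above whole animal on the log2 scale, and hoe2, a gene related to a pigment transporter, 3.97 (SE 0.259) above it. The muscle gene bt was among the lowest, at -4.36 (SE 0.294).

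The wing disc, the primordium of the adult wing and notum, held some patterning and cell cycle transcripts above the other 4 tissues. The ecdysone-inducible disc gene ImpE2 had the largest difference, log2 3.64 (SE 0.328, adjusted p = 4.63e-06). The transcription factor gene of the Hedgehog pathway, ci, was higher by 2.86 (SE 0.289), the homeobox genes zfh2 and mirr by 2.42 (SE 0.239) and 1.88 (SE 0.20), and the Notch target gene E(spl)m7-HLH by 1.54 (SE 0.228). Of 27 measured disc patterning genes, 12 passed the test, each higher, and 15 did not (camera adjusted p = 2.73e-08; adjusted p = 0.128 with an estimated correlation), with 14 higher when adjusted over the list alone. The gap junction gene Inx3 was higher by 2.75 (SE 0.227), and Dlish, which encodes a partner of the Fat pathway protein Dachs, by 2.55 (SE 0.258). Of 38 DNA replication and mitosis genes, 27 passed, each higher, and 11 did not (camera adjusted p = 1.37e-20), with 29 higher when adjusted over the list alone. Among them were fzy at 2.20 (SE 0.263), PCNA, the sliding clamp gene of DNA polymerase, at 2.08 (SE 0.244), SMC2 at 1.98 (SE 0.233) and Mcm3 at 1.96 (SE 0.215).

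Some V-ATPase genes lay below the mean of the other 4 tissues in the wing disc. Among 20 subunit genes of the vacuolar proton pump, or V-ATPase, 12 passed the test, each lower, and 8 did not (camera adjusted p = 1.49e-07; adjusted p = 0.185 with an estimated correlation), with 13 lower when adjusted over the list alone. By pairs, V-ATPase genes were lower in wing disc than in epidermis (adjusted p = 8.49e-06), salivary gland (1.13e-05) and midgut (6.36e-07), and did not pass against central nervous system (0.0654). VhaAC39-1 was lower at -1.72 (SE 0.194) and Vha14-1 at -1.64 (SE 0.241). The carbonic anhydrase gene CAH7 was lower at -3.52 (SE 0.327, adjusted p = 5.54e-06), and the growth factor genes Idgf3 and Idgf2 at -2.71 (SE 0.179) and -1.95 (SE 0.218). The fat body list had 6 of 14 members lower, 1 higher, CG6180, which has no name and was named after its value was seen, at 0.57, and 7 not past the test (camera adjusted p = 7.45e-06; adjusted p = 0.119 with an estimated correlation; 8 lower and 1 higher adjusted over the list alone). By pairs, fat body genes were lower in wing disc than in epidermis (adjusted p = 6.36e-07), salivary gland (3.51e-07) and central nervous system (0.00821), and did not pass against midgut (0.111). Relative to a mean that includes epidermis with muscle and midgut, muscle genes had 6 of 21 past the test, each lower (13 adjusted over the list alone; camera adjusted p = 0.000154; adjusted p = 0.38 with an estimated correlation), and digestive enzyme genes 24 of 39, each lower (29 adjusted over the list alone; camera adjusted p = 8.91e-11; adjusted p = 0.155 with an estimated correlation). By pairs, muscle genes were lower in wing disc than in epidermis (adjusted p = 5.51e-24), and did not pass against salivary gland (0.155), midgut (0.639) and central nervous system (0.733). By pairs, digestive enzyme genes were lower in wing disc than in midgut (adjusted p = 3.61e-54), and did not pass against epidermis (0.852), salivary gland (0.212) and central nervous system (0.605). In all, 1669 features differed from the other 4 tissues, 799 higher and 870 lower. The count was 1053 without wing disc replicate 2. The balance turned to 861 higher and 784 lower in the values as deposited, 669 higher and 546 lower when arrays were scaled to a common spread and 619 higher and 551 lower without wing disc replicate 3. Against whole animal, 4215 of 10815 features passed, 1989 higher and 2226 lower, with 36.1% higher over features measured on all 15 arrays and 50.5% after centring within classes, and 580 were higher and 1365 lower at a minimum difference of log2 1. Without that minimum, 2701 passed without wing disc replicate 2. The small heat shock gene Hsp26 stood 3.51 (SE 0.24) above whole animal and Lsp2 at -4.58 (SE 0.296).

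The midgut had the most differences, 2506 of 8432 features against the other 4 tissues, 1196 higher and 1310 lower. The balance turned to 800 higher and 522 lower at a minimum difference of log2 1, and to 1046 higher and 1004 lower on the 12 arrays left after leaving out epidermis, salivary gland and midgut replicate 3. It turned to 1021 higher and 938 lower, 894 higher and 891 lower and 1019 higher and 901 lower without midgut replicates 1, 2 and 3. Digestive enzymes were among them. The serine protease gene Jon99Cii was higher by log2 6.19 (SE 0.392, adjusted p = 7.29e-09), the trypsin gene thetaTry by 6.04 (SE 0.346), and the lysozyme genes LysE and LysS by 5.94 (SE 0.405) and 5.87 (SE 0.291). CG11912, a gene with no name, had the largest difference at 6.99 (SE 0.22, adjusted p = 6.08e-12). Of 39 measured enzyme genes, 38 passed the test, each higher, and 1 did not (camera adjusted p = 4.60e-77), with 39 higher when adjusted over the list alone. Jonah, trypsin and lysozyme genes lie in families of near-identical copies, so the value of any 1 member is uncertain.

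Members of the immune and V-ATPase lists were also higher in the midgut. PGRP-SC2, which encodes an enzyme that degrades bacterial peptidoglycan, was higher by log2 5.82 (SE 0.40), the attacin gene AttD by 1.85 (SE 0.296) and PGRP-LB by 1.27 (SE 0.229). These were the 3 of 8 immune genes past the test (3 adjusted over the list alone), a list that did not pass camera (adjusted p = 0.0660) except without epidermis replicate 3 (0.00432) and on those 12 arrays (0.036). Of 20 V-ATPase genes, 9 were higher, 1 was lower and 10 did not pass (camera adjusted p = 0.000607; adjusted p = 0.351 with an estimated correlation), and adjusted over the list alone 10 were higher and 1 lower. By pairs, V-ATPase genes were higher in midgut than in wing disc (adjusted p = 6.36e-07) and central nervous system (0.000387), and did not pass against epidermis (0.101) and salivary gland (0.16). The largest was Vha100-5 at 4.32 (SE 0.252), and the lower gene was VhaM9.7-a at -0.77, named after its value was seen. The P450 gene shd, which converts ecdysone into the active hormone 20-hydroxyecdysone, was higher by 3.23 (SE 0.526), the lipase gene bmm by 2.70 (SE 0.269) and the glutamine synthetase gene Gs2 by 2.49 (SE 0.306).

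Some DNA replication, ribosomal protein and secretory pathway genes lay below the mean of the other 4 tissues in the midgut, though none of the 3 list calls passed with an estimated correlation. Of 38 DNA replication and mitosis genes, 22 passed the test, each lower, and 16 did not (camera adjusted p = 3.32e-07; adjusted p = 0.12 with an estimated correlation; 24 lower adjusted over the list alone). By pairs, DNA replication genes were lower in midgut than in wing disc (adjusted p = 1.30e-16) and central nervous system (2.84e-10), and did not pass against epidermis (0.0785) and salivary gland (0.215). PCNA was lower at -2.03 (SE 0.244) and RnrL, which encodes the large subunit of ribonucleotide reductase, at -1.60 (SE 0.25). Cytosolic ribosomal protein genes had 13 of 29 past the test, each lower (14 adjusted over the list alone; camera adjusted p = 0.00150; adjusted p = 0.522 with an estimated correlation), among them RpL27 at -0.92 (SE 0.183). By pairs, ribosomal protein genes were lower in midgut than in epidermis (adjusted p = 0.0323), salivary gland (0.000112) and wing disc (0.00115), and did not pass against central nervous system (0.12). Of 35 secretory pathway genes, 14 were lower and 21 did not pass (16 lower adjusted over the list alone; camera adjusted p = 0.000367; adjusted p = 0.376 with an estimated correlation), with Spase25 at -2.24 (SE 0.201). By pairs, secretory pathway genes were lower in midgut than in epidermis (adjusted p = 0.0292) and salivary gland (2.90e-22), and did not pass against wing disc (0.166) and central nervous system (0.441). Relative to a mean that includes the salivary gland, salivary gland genes had 5 of 8 past the test, each lower (5 adjusted over the list alone; camera adjusted p = 0.00479; adjusted p = 0.273 with an estimated correlation). By pairs, salivary gland genes were lower in midgut than in salivary gland (adjusted p = 1.89e-35), and did not pass against epidermis (0.892), wing disc (0.852) and central nervous system (0.889). The Hedgehog pathway gene ci was lower at -3.26 (SE 0.289). Against whole animal, 3273 of 11354 features passed, 1557 higher and 1716 lower, with 34.6% higher over features measured on all 15 arrays, and 473 were higher and 864 lower at a minimum difference of log2 1. Without that minimum, the count was 2132 without midgut replicate 1, 1766 without midgut replicate 3 and 5006 with array weights. CG11912 stood 3.54 (SE 0.197) above whole animal, LysS 2.97 (SE 0.26) and apolpp at -4.92 (SE 0.44).

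Some neuronal transcripts were higher in the central nervous system than in the other 4 tissues. Nrt, which encodes the cell adhesion protein neurotactin, was higher by log2 3.88 (SE 0.223, adjusted p = 3.26e-08), Ggamma30A, a G protein subunit gene, by 3.78 (SE 0.242), Gabat, which encodes GABA transaminase, by 3.72 (SE 0.245) and the neuroendocrine gene 7B2 by 3.34 (SE 0.229). The pan-neuronal gene elav was higher by 2.86 (SE 0.272), wor and brat, genes that act in neuroblasts, by 2.40 (SE 0.328) and 2.38 (SE 0.264), and nrv3, a sodium pump subunit gene, by 2.28 (SE 0.263). Of 26 neuron and glia genes, 10 were higher, 1 was lower and 15 did not pass (camera adjusted p = 0.000189; adjusted p = 0.522 with an estimated correlation), and adjusted over the list alone 11 were higher and 1 lower. The lower gene was Rbp9 at -1.40, named here after its value was seen. That camera call was lost without epidermis replicate 1 (adjusted p = 0.0578) and over features measured on all 15 arrays (0.25). Of 38 DNA replication and mitosis genes, 19 passed, each higher, and 19 did not (camera adjusted p = 3.74e-08; adjusted p = 0.0994 with an estimated correlation; 23 higher adjusted over the list alone), with SMC2 at 1.88 (SE 0.233) and Mcm2 at 1.42 (SE 0.213). By pairs, DNA replication genes were higher in central nervous system than in epidermis (adjusted p = 1.16e-07), salivary gland (4.08e-09) and midgut (2.84e-10), lower than in wing disc (0.0132).

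Some disc genes were higher in the central nervous system as well, with zfh2 at log2 2.16 (SE 0.239), sna, a zinc finger gene, at 1.92 (SE 0.276) and trn at 1.46 (SE 0.224). The disc list had 5 of 27 members higher, 1 lower and no camera call (adjusted p = 0.453; 5 higher and 1 lower adjusted over the list alone), with a median of -0.10 and a mean of 0.14. VhaM9.7-a, a proton pump subunit gene, was higher by 2.74 (SE 0.237), while 7 of 20 V-ATPase genes were lower (1 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.0248; adjusted p = 0.46 with an estimated correlation). The call for V-ATPase genes was lost without epidermis replicate 2 (adjusted p = 0.0566), without epidermis replicate 3 (0.0546) and over features measured on all 15 arrays (0.088). By pairs, V-ATPase genes were lower in central nervous system than in salivary gland (adjusted p = 0.0217) and midgut (0.000387), and did not pass against epidermis (0.0582) and wing disc (0.0654). Pepck1, a gene of gluconeogenesis, was lower at -3.26 (SE 0.21, adjusted p = 8.34e-08), the tropomyosin gene Tm2 at -2.39 (SE 0.309) and the cuticle gene Cpr49Ac at -2.74 (SE 0.376). Relative to a mean that includes epidermis with muscle, muscle genes had 10 of 21 past the test, each lower (12 adjusted over the list alone; camera adjusted p = 7.65e-06; adjusted p = 0.323 with an estimated correlation). By pairs, muscle genes were lower in central nervous system than in epidermis (adjusted p = 6.72e-25) and salivary gland (0.0335), and did not pass against wing disc (0.733) and midgut (0.309). Cuticle genes had 8 of 23, each lower (8 adjusted over the list alone; camera adjusted p = 0.000661; adjusted p = 0.117 with an estimated correlation). By pairs, cuticle genes were lower in central nervous system than in epidermis (adjusted p = 1.11e-10) and wing disc (0.0265), and did not pass against salivary gland (0.212) and midgut (0.787). Digestive enzyme genes had 25 of 39, each lower (26 adjusted over the list alone; camera adjusted p = 3.40e-13; adjusted p = 0.12 with an estimated correlation). By pairs, digestive enzyme genes were lower in central nervous system than in midgut (adjusted p = 1.02e-58), and did not pass against epidermis (0.852), salivary gland (0.0572) and wing disc (0.605).

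In all, 1866 features differed between the central nervous system and the other 4 tissues, 1008 higher and 858 lower, and the count was 1159 without central nervous system replicate 2 and 1182 without replicate 3. The balance turned to 443 higher and 493 lower at a minimum difference of log2 1, 721 higher and 735 lower without central nervous system replicate 1 and 994 higher and 1025 lower on the 12 arrays. Against whole animal, 4305 of 10473 features passed, 2077 higher and 2228 lower, a balance that turned to 2268 higher and 2095 lower in the values as deposited. Over features measured on all 15 arrays there were 1033 higher and 1552 lower, and 622 were higher and 1432 lower at a minimum difference of log2 1. The neuropeptide genes FMRFa, at log2 3.02 (SE 0.284) on n = 2 arrays, and Ilp2, an insulin-like peptide gene, at 2.88 (SE 0.198), stood above whole animal, and the trypsin gene alphaTry at -5.02 (SE 0.363).

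The lists of each tissue's own genes, and the secretory pathway and DNA replication lists, were set against each other tissue in turn. By pairs, muscle genes were higher in epidermis than in salivary gland (adjusted p = 6.83e-15), wing disc (5.51e-24), midgut (6.63e-13) and central nervous system (6.72e-25). By pairs, cuticle genes were higher in epidermis than in salivary gland (adjusted p = 5.70e-07), wing disc (8.57e-08), midgut (3.76e-06) and central nervous system (1.11e-10). By pairs, salivary gland genes were higher in salivary gland than in epidermis (adjusted p = 3.47e-49), wing disc (3.36e-35), midgut (1.89e-35) and central nervous system (5.52e-36). By pairs, secretory pathway genes were higher in salivary gland than in epidermis (adjusted p = 2.59e-15), wing disc (8.31e-15), midgut (2.90e-22) and central nervous system (1.37e-17). By pairs, disc genes were higher in wing disc than in epidermis (adjusted p = 1.16e-06), salivary gland (7.30e-08), midgut (1.57e-05) and central nervous system (0.000289). By pairs, DNA replication genes were higher in wing disc than in epidermis (adjusted p = 2.39e-17), salivary gland (1.21e-16), midgut (1.30e-16) and central nervous system (0.0132). By pairs, digestive enzyme genes were higher in midgut than in epidermis (adjusted p = 1.06e-67), salivary gland (4.36e-67), wing disc (3.61e-54) and central nervous system (1.02e-58). By pairs, neuron and glia genes were higher in central nervous system than in epidermis (adjusted p = 0.0372), salivary gland (0.00358), wing disc (1.21e-08) and midgut (0.0302). These pairs were tested at the preset correlation alone. With an estimated correlation, camera did not pass against the other 4 tissues for neuron and glia genes (adjusted p = 0.522), disc genes in wing disc (0.128) or muscle genes in epidermis (0.0575). The call for neuron and glia genes against the other 4 was also lost without epidermis replicate 1 (0.0578) and over features measured on all 15 arrays (0.25).

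**Figure D3:**
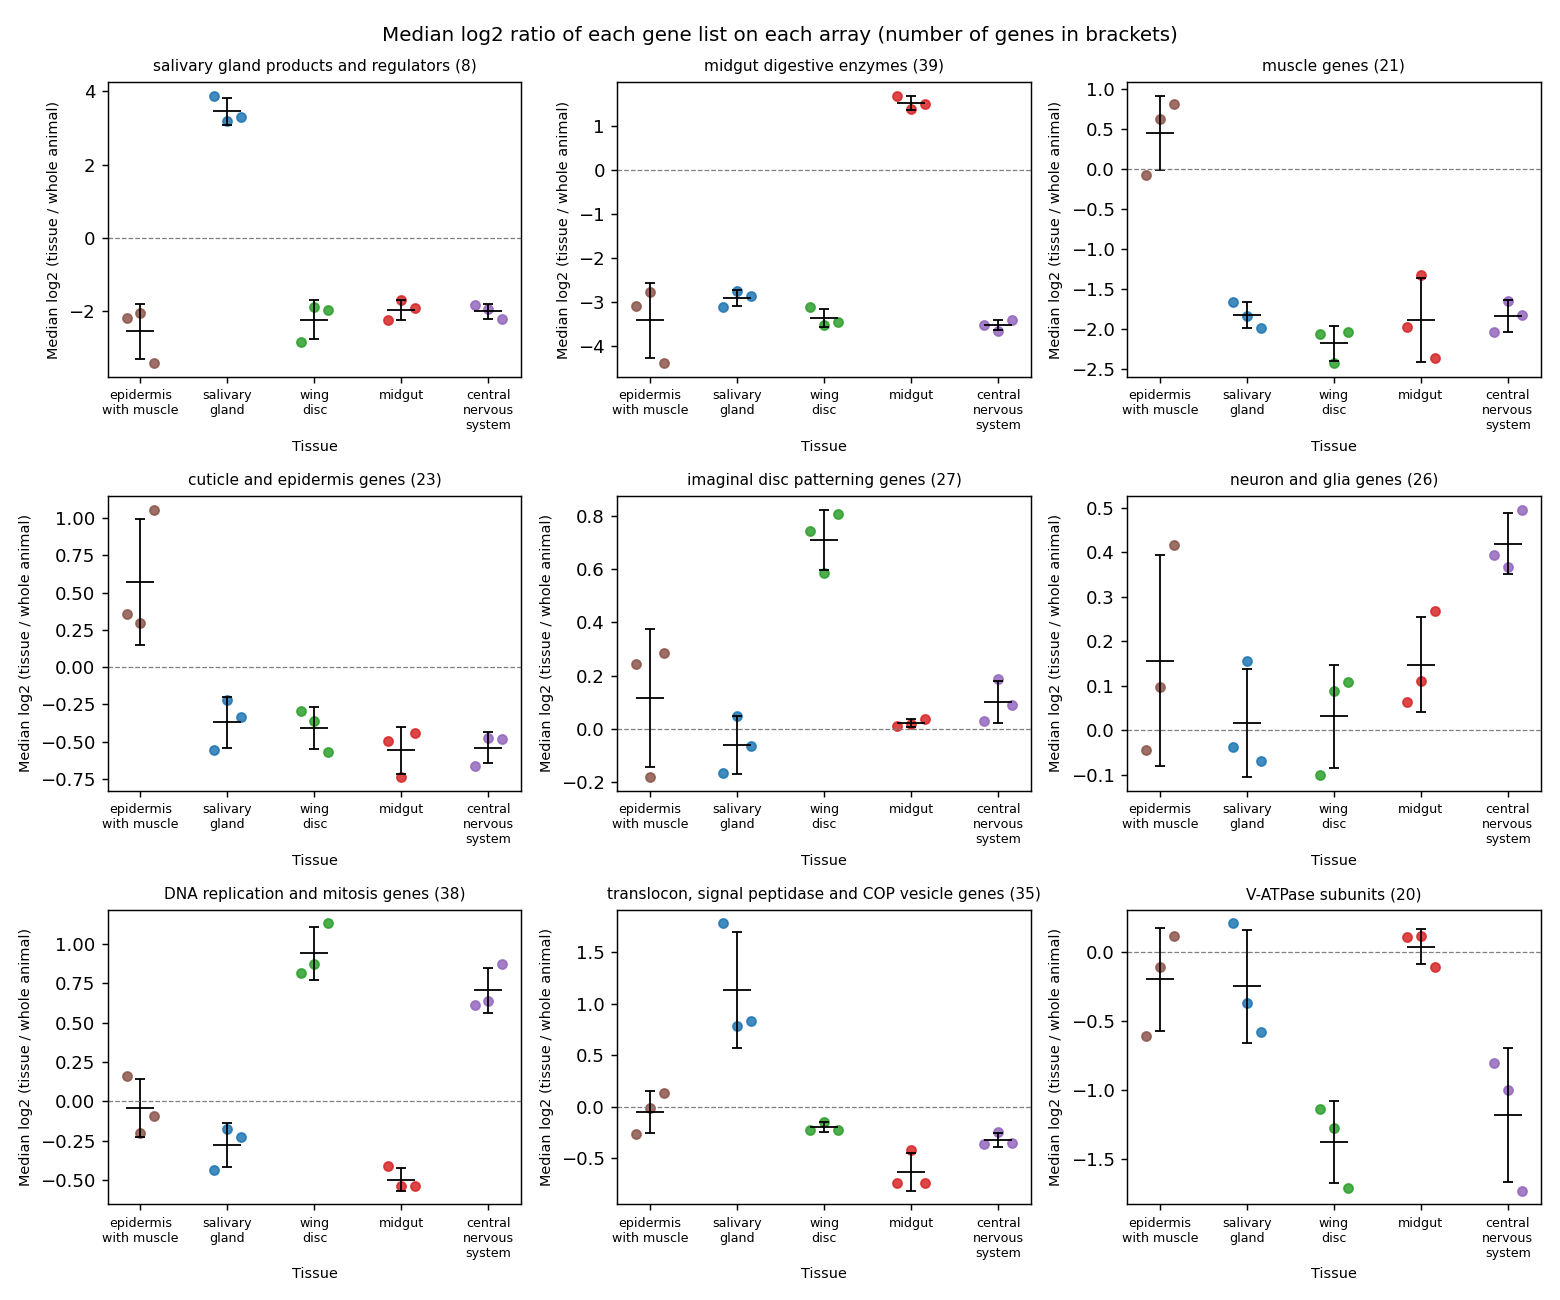
Each of the 9 panels shows the median log2 ratio of tissue over whole animal of 1 gene list on each array (points), with the mean of the 3 arrays (dash) and their SD (bar). DNA replication and mitosis genes had medians of 0.82 to 1.13 on the wing disc arrays and -0.54 to -0.41 on the midgut arrays, and secretory pathway genes 0.78 to 1.78 on the salivary gland arrays.

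Between pairs of tissues, the number of features past the limma test ranged from 513 of 9277 for wing disc against central nervous system to 2611 of 9729 for midgut against central nervous system. The former count was 312 without wing disc replicate 2, 328 without central nervous system replicate 2, 332 without central nervous system replicate 3 and 794 with array weights. The other pairs were epidermis against salivary gland (1072; 627 when fitted to its own arrays alone), wing disc (1092; 1741 with array weights), midgut (1689) and central nervous system (1484), salivary gland against wing disc (1797), midgut (1532) and central nervous system (1893), and wing disc against midgut (2487).

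Features at least log2 1 higher in 1 tissue than in each of the others, with each of the 4 differences past the test, numbered 501 in midgut, 241 in epidermis, 187 in salivary gland, 100 in central nervous system and 48 in wing disc. Of these, 443, 205, 152, 84 and 34 were named genes. The widest margins belonged to CG11912, CG6271 and thetaTry in midgut, CG5171, yellow-d2 and CG11854 in epidermis, Eig71Ee, Sgs5 and CG9040 in salivary gland, Ggamma30A, CG9686 and Gabat in central nervous system, and ImpE2, CG15905 and St2 in wing disc. St2, a sulfotransferase gene, was log2 2.34 (SE 0.328) above the other 4 tissues. The count for the central nervous system was 63 without wing disc replicate 1, 64 without wing disc replicate 2 and 47 over features measured on all 15 arrays.

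The nuclear receptor genes EcR and usp, whose products form the ecdysone receptor, the early gene br, the receptor genes Hr39 and ftz-f1 and the Hox gene Dfd gave 30 tests against the other 4 tissues. With limma, 0 of the 30 passed after adjustment and 3 had an unadjusted p under 0.05. The lowest adjusted p was that of Dfd in salivary gland, 0.72 (SE 0.241, adjusted p = 0.0571), and EcR in epidermis was at 1.10 (SE 0.448, adjusted p = 0.153), or adjusted p = 0.0343 without epidermis replicate 1. Only 2 of 8 Hox genes were found among measured rows annotated with 1 gene, and only Dfd was tested, so the Hox list was not tested as a group. The wider ecdysone pathway list of 23 genes had 3 members past the test in the central nervous system, each lower, including ImpE2 at -1.57 (SE 0.328) (2 adjusted over the list alone; camera adjusted p = 0.0446; adjusted p = 0.376 with an estimated correlation). Leaving out any of salivary gland replicate 3, epidermis replicate 3, wing disc replicates 1 and 2, midgut replicates 1, 2 and 3 or central nervous system replicates 1 and 2 ended that camera call (adjusted p = 0.07, 0.089, 0.105, 0.114, 0.102, 0.097, 0.0513, 0.11 and 0.086). By pairs, ecdysone pathway genes were lower in central nervous system than in epidermis (adjusted p = 0.0302), and did not pass against salivary gland (0.272), wing disc (0.155) and midgut (0.51). In epidermis 3 members were higher (3 adjusted over the list alone; camera adjusted p = 0.116, and 0.0219 without epidermis replicate 1).

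Other camera calls rested on few members or single arrays. Ribosomal protein genes were called higher in salivary gland, with 2 of 29 past the test (adjusted over the list alone 2; camera adjusted p = 0.0131; adjusted p = 0.541 with an estimated correlation), and the call was lost without epidermis replicate 3 (0.0513), salivary gland replicate 1 (0.0574) or salivary gland replicate 3 (0.142). By pairs, ribosomal protein genes were higher in salivary gland than in midgut (adjusted p = 0.000112), and did not pass against epidermis (0.153), wing disc (0.892) and central nervous system (0.12). Disc genes were called lower there, with 9 of 27 lower and 1 higher (adjusted over the list alone 10 and 3; camera adjusted p = 0.0273; adjusted p = 0.541 with an estimated correlation). By pairs, disc genes were lower in salivary gland than in wing disc (adjusted p = 7.30e-08), and did not pass against epidermis (0.441), midgut (0.892) and central nervous system (0.0921). The lower genes included zfh2 at -2.51 (SE 0.279) (n = 2), mirr at -1.41 (SE 0.20) and ci at -1.38 (SE 0.289). The higher gene was Dad, an inhibitor of Dpp signalling, at 1.30, named after its value was seen, and the call was lost without salivary gland replicate 1 (0.493), salivary gland replicate 3 (0.139), wing disc replicate 1 (0.057), wing disc replicate 2 (0.0647) or midgut replicate 3 (0.0652). Immune genes were called lower in the central nervous system, with 3 of 8 past the test (3 adjusted over the list alone; camera adjusted p = 0.0281; adjusted p = 0.46 with an estimated correlation), but not without wing disc replicate 1 (0.149), wing disc replicate 2 (0.13), central nervous system replicate 1 (0.273) or central nervous system replicate 2 (0.216). By pairs, immune genes were lower in central nervous system than in salivary gland (adjusted p = 0.0295) and midgut (0.0186), and did not pass against epidermis (0.459) and wing disc (0.289). DNA replication genes were called lower in epidermis (camera adjusted p = 0.00277; adjusted p = 0.305 with an estimated correlation), but not without epidermis replicate 2 (0.0713), and 2 of 38 passed the test there, or 0 adjusted over the list alone. By pairs, DNA replication genes were lower in epidermis than in wing disc (adjusted p = 2.39e-17) and central nervous system (1.16e-07), and did not pass against salivary gland (0.629) and midgut (0.0785). Hemocyte genes (14 measured), testis and germline genes (9), mitochondrial respiratory chain and ATP synthase genes (57) and heat shock genes (11) gave 20 camera tests against the other 4 tissues, of which 0 passed, 0 had an unadjusted p under 0.05 and 0 passed fry.

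Against whole animal, 127 features were higher in all 5 tissues and 199 were lower in all 5, out of 8432 tested. Independent lists of the same sizes would share 0.73 and 3.65. Simulated unchanged tissues read against 1 shared reference gave a mean of 107 each way, where the reference's spread was assumed equal to that between arrays of a tissue. Part of the excess may thus come from a shared reference, but its real spread was not measured, so how much is not known. A set of 5 heat-inducible chaperone genes were among the highest, with Hsp26 between log2 2.85 and 3.86, Hsp68 between 2.82 and 3.96, Hsp22 between 2.72 and 3.58, Hsp27 between 1.45 and 2.72 and DnaJ-1 between 1.81 and 2.64 over the 5 tissues. The hormone gene ITP, at 1.57 to 2.46, and the juvenile hormone receptor gene Met, at 1.44 to 2.26, were also higher in all 5. Of 13 measured heat shock and chaperone genes in wing disc, 6 passed above whole animal, and the constitutive chaperone gene Hsc70-4 lay between -0.71 and 0.33 over the tissues. Genes lower in all 5 included the alkaline phosphatase gene Alp8, at -2.98 to -3.72, the lipid carrier gene apolpp, at -2.71 to -4.92, the prophenoloxidase genes PPO1 and PPO2 of crystal cells, and Hml, a hemocyte gene, at -1.48 to -2.75. DnaJ-1, ITP, Met, Alp8, PPO1, PPO2 and Hml were named after their values were seen. The whole animal also holds tissues that were not dissected here, among them fat body and blood cells.

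**Figure D4:**
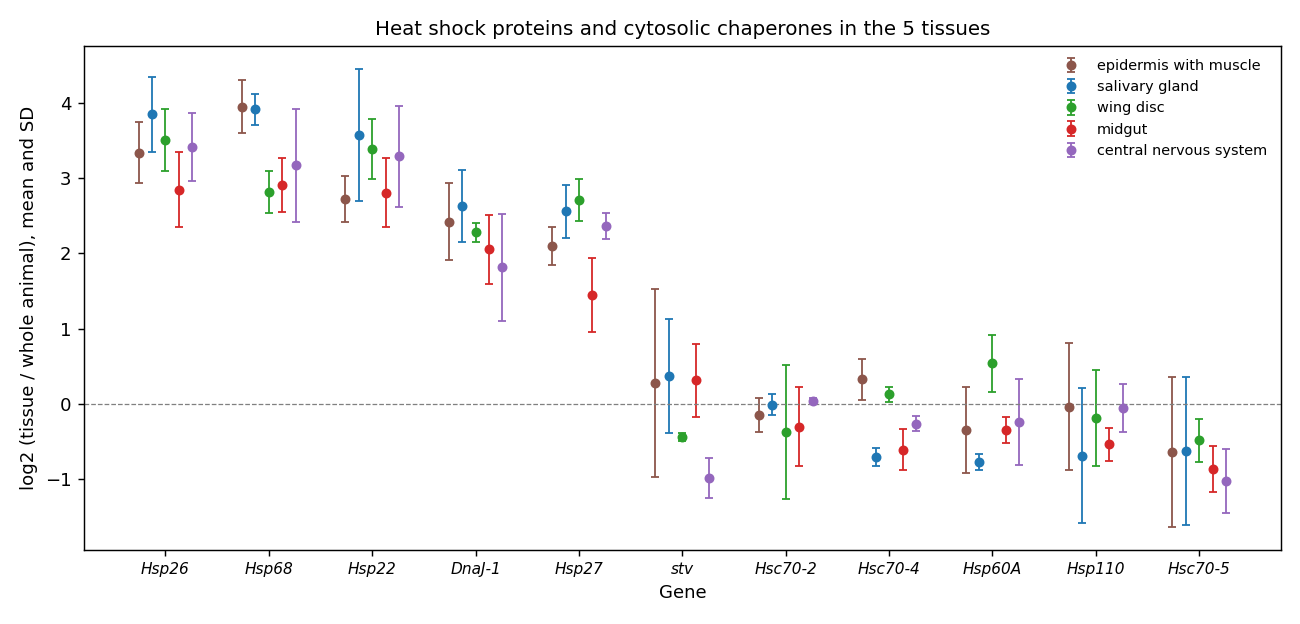
Mean log2 ratio of tissue over whole animal of 11 heat shock and chaperone genes in each of the 5 tissues, with the SD between arrays as bars. Hsp22, Hsp26, Hsp27, Hsp68 and DnaJ-1 lay above 1 in each tissue, and Hsc70-4 between -0.71 and 0.33.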

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

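All tests of the 3 patterns weighed here, on fat body genes, heat shock genes and the gap between dim and bright rows, were chosen only after the result was seen.

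Several lists moved in opposite directions relative to whole animal in 2 tissues, with a tested difference between those tissues (camera, preset correlation, adjusted over pairs and lists). Salivary gland genes did so in 4 of the 10 pairs of tissues, higher in salivary gland and lower in the other 4 (adjusted p from 3.47e-49 to 3.36e-35). Midgut digestive enzymes did so in 4 pairs, those of midgut with each other tissue (1.06e-67 to 3.61e-54). Muscle genes did so in 4 pairs, those of epidermis with each other tissue (6.72e-25 to 6.63e-13). Their median ratio in epidermis was -0.07 log2 on replicate 1, against 0.62 on replicate 2 and 0.80 on replicate 3. Cuticle genes moved in opposite directions in 2 pairs, epidermis against midgut (3.76e-06) and against central nervous system (1.11e-10). DNA replication and mitosis genes did so in 2 pairs, higher in wing disc and lower in midgut (1.3e-16), and lower in midgut and higher in central nervous system (2.84e-10). Secretory pathway genes did so in 1 pair, higher in salivary gland and lower in midgut (2.9e-22). The pairs were tested at the preset correlation alone. With an estimated correlation, 0 of 85 camera tests of a list against whole animal passed (23 had an unadjusted p under 0.05). At the preset correlation 48 passed, and by fry 65.

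Some fat body transcripts had mean levels within log2 1 of whole animal on the 3 salivary gland arrays, with Lsp2 at -0.03 (SD 0.503), Fbp2 at -0.31 (SD 0.115) and Fbp1 at -0.65 (SD 1.29), while 5 of 14 measured list members, among them apolpp at -2.71, had means more than log2 1 below it. If fat body of the whole animal's makeup had been left on the glands, all list members were predicted near the level of Lsp2. Of 13 compared, 2, apolpp and Idgf4, lay more than log2 1 below it on each gland array. That was fewer than the 3 that had been set as the bound, so this cannot be told apart from other sources. The prediction holds only for members made mainly in fat body, and CtsL1 (2.175) and bmm (1.416) were above whole animal in midgut. The level of apolpp goes against this source, but it is 1 member. Fat body of another makeup, or transcription in the gland itself, also stays open, since apolpp minus Lsp2 was -2.68 (SD 0.333, n = 3) and no fat body sample was hybridised. None of the 15 fat body genes found among measured rows annotated with 1 gene was in another list, and Lsp1alpha, Lsp1beta, Lsp1gamma and Adh were not found there. Which of them the gland itself transcribes was not tested.

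Hsp22, Hsp26, Hsp27, Hsp68 and DnaJ-1 were above whole animal in all 5 tissues, with a median log2 ratio of 2.82. After centring within classes of dim and bright rows the median was 3.02 and 25 of 25 tests stayed past the threshold. That centring could not have removed a median of 2.82, since the gap between dim and bright rows was at most 1.02 log2 on any array. An offset of that size falls short of the median ratio, but an offset particular to these genes was not tested. A gene-specific dye effect stays open, because the tissue was always in Cy5. As the whole cause, it would give a gene the same ratio in each tissue. By the limma F test 2 of the 5 genes, Hsp27 (adjusted p = 0.0073) and Hsp68 (0.0149), differed among tissues, which goes against it as the whole cause for them. Hsp22 (0.304), Hsp26 (0.179) and DnaJ-1 (0.333) did not pass, and a part common to all tissues stays confounded with the dye. A stress response of dissected tissue stays open as an untested hypothesis, since the count of 5 of 11 list members against 127 of 8432 features higher in all 5 tissues (Fisher's exact test, two-sided, p = 3.08e-07) restates the observation that prompted it and treats genes read against 1 reference as independent. The design does not separate dye from dissection, so the pattern is not called biological.

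Rows measured on 6 to 11 arrays (4285) sat above rows measured on all 15 (4673) by 0.0657 log2 on epidermis replicate 2 to 1.02 on salivary gland replicate 3. A property of each tissue's RNA is argued against as the whole cause, since arrays of 1 tissue differed by up to 0.844 while tissue means differed by 0.502 at most. As a part of the cause it stays open, since the share of the variance between tissues was 36.3% (permutation p = 0.261). With 3 arrays per tissue that test cannot exclude a tissue effect, and single arrays tend to range more widely than means. The authors' filter on dim rows stays open, with Spearman's rho of -0.246 between the gap and the number of rows measured (permutation p = 0.375, adjusted 0.375; r = -0.299, p = 0.281; r = -0.709 without epidermis replicate 3 and wing disc replicate 3, and -0.518 within tissues, p = 0.0424), while the array with the fewest rows had a gap of 0.0964, under the median of 0.273, a bound set against this explanation and dropped after its value was seen because 1 array excludes nothing. A setting of each array that the code in its title records is a candidate explanation, with r = 0.679 between the gap and the difference of the code's parts (permutation p = 0.00451, adjusted over the 2 relations 0.00902; rho 0.667, adjusted p = 0.0153) and 0.757 within tissues (p = 0.023), but r was 0.504 without salivary gland replicate 3 and central nervous system replicate 1, so it rests in part on those arrays. What the code means is not given in the sources used here, and no biological explanation beyond the tissue was tested.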

How the results depend on the processing

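Of the alternatives below, centring within classes of dim and bright rows, ratios under 20 steps set to 20 steps, the 12 arrays and named genes only were chosen after seeing the data. No named gene and no list reversed its direction under an alternative where the main or the alternative result was past the threshold. Of 9968 values of named genes under the alternatives, 9552 kept their direction and side of the threshold, 379 lost their call and 3 gained one. The other 34 changed direction, with neither the main nor the alternative result past the threshold. Of 4230 values of single list tests these numbers were 4056, 73, 14 and 87, in the same order. The cause was not tested where none is given. Signal over background is not in the sources used here, so how far dim features limit the values was not measured. The number of rows measured fell from 13505 to 7747.

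Over features measured on all 15 arrays, where fewer were tested, 1531 features passed against whole animal in epidermis, 2007 in salivary gland, 2609 in wing disc, 1886 in midgut and 2585 in central nervous system, and 47 were highest in the central nervous system. There, 38.2% of calls against whole animal were higher in epidermis (49.3% in the main analysis), 26.9% in salivary gland (47.6%), 36.1% in wing disc (47.2%) and 34.6% in midgut (47.6%). Arrays were centred over all rows, and rows measured on all 15 arrays then had medians of -0.344 to -0.0331 log2. The lower shares thus follow in part from the centring. With array weights 5006 features passed for midgut against whole animal, 1741 for epidermis against wing disc and 794 for wing disc against central nervous system. With only the arrays compared in the fit, and so fewer degrees of freedom, 1542 passed for epidermis against whole animal and 627 for epidermis against salivary gland. Requiring a difference of at least log2 1 left 1369, 1631, 1945, 1337 and 2054 against whole animal (epidermis, salivary gland, wing disc, midgut, central nervous system) and 758, 860, 1322 and 936 against the other 4 (salivary gland onward), and a minimum of log2 2 left 122, 70, 5, 284 and 33 features highest in 1 tissue. Camera with an estimated correlation called 0 lists against whole animal and 5 against the other 4. On the 12 arrays 2521 features passed for salivary gland against whole animal and 631 for epidermis against the other 4. The counts stayed within 1.5 times the main count under the other alternatives, which kept 69.2% to 99.7% of the main calls when arrays were scaled to a common spread, 74.4% to 98.3% when centred within classes and 91.6% to 97.9% as deposited.

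Leaving out 1 array at a time gave, against whole animal, 1596 to 2823 features in epidermis (1652 without its replicate 1, 1596 without 2), 2150 to 4209 in salivary gland (lowest without its replicate 3), 2701 to 4413 in wing disc (without 2), 1766 to 3454 in midgut (2132 without 1, 1766 without 3) and 2964 to 4469 in central nervous system. Against the other 4 tissues the ranges were 594 to 1152 (lowest without epidermis 3), 825 to 1608 (without salivary gland 1), 1053 to 1781 (without wing disc 2), 1785 to 2574 and 1159 to 1977 (1159 without central nervous system 2, 1182 without 3). The pairs ranged over 784 to 1174 (epidermis and salivary gland), 745 to 1398 (wing disc), 1346 to 1754 (midgut), 1018 to 1662 (central nervous system), 1244 to 1906 (salivary gland and wing disc), 1133 to 1591 (midgut), 1372 to 1993 (central nervous system), 1809 to 2621 (wing disc and midgut), 312 to 555 (central nervous system; 312 without wing disc 2, 328 without central nervous system 2, 332 without 3) and 2005 to 2754 (midgut and central nervous system). The F test gave 2979 to 3728, features highest in 1 tissue 197 to 276, 146 to 234, 35 to 48, 421 to 493 and 63 to 100 (63 without wing disc 1, 64 without 2), and list calls 47 to 49 against whole animal and 33 to 37 against the other 4. The share of higher calls in epidermis moved to 38.6% without its replicate 1 and 35.6% without 2 against whole animal (49.3%), and to 83.3% without 3 against the other 4 (69.1%).

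Whether the replicate numbers pair the arrays is not settled. The 30 pairs of arrays of different tissues with the same number had deviations correlated at 0.014 on average (-0.487 to 0.352, 11 over 0.1), and the 60 pairs with different numbers at -0.00684. By contrast, 9 of 15 arrays correlated best with their own number, more than an even spread over the 3 numbers would give. Replicate 3 had the fewest rows measured in each tissue, from 7747 in epidermis to 10369 in salivary gland. With the replicate number as a block, 2826 features passed for epidermis against whole animal and 497 for wing disc against central nervous system, and no count moved by over 1.5 times.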

Other observations

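Genes of hemocytes, the blood cells, fell relative to whole animal more often than they rose in each dissected tissue. Of the hemocyte list, 7 of 14 genes were lower in epidermis, 7 of 16 in salivary gland, 8 of 15 in wing disc, 9 of 15 in midgut and 11 of 15 in central nervous system, with 1, 2, 1 and 1 higher in the last 4 (camera adjusted p = 0.00168, 0.0306, 0.0143, 1.33e-05 and 0.00199; with an estimated correlation the adjusted p-values were 0.112, 0.168, 0.117, 0.112 and 0.112). Adjusted over the list alone, 9, 9, 11, 10 and 11 were lower. Genes named after their values were seen were Hml, which encodes a clotting protein of hemocytes, at -1.48, -2.40, -2.41, -2.75 and -2.73 (SE 0.355) log2, and the prophenoloxidase gene PPO1 at -2.54, -1.75, -2.52, -3.0 and -3.51 (SE 0.389), in the same order of tissues. Miox, a gene of inositol breakdown, at -2.31, -1.93, -3.18, -3.32 and -3.0 (SE 0.205), and the alkaline phosphatase gene Alp4, at -2.91, -3.27, -2.99, -3.59 and -3.39 (SE 0.326 to 0.40), were lower in all 5 tissues too.

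Some cytosolic ribosomal protein genes were above whole animal in salivary gland and wing disc. In salivary gland 12 of 32 passed the limma test, each higher (median log2 0.40; 14 adjusted over the list alone; camera adjusted p = 0.00262; adjusted p = 0.253 with an estimated correlation), and in wing disc 8 of 30, each higher (median 0.30; 8 adjusted over the list alone; camera adjusted p = 0.00556; adjusted p = 0.393 with an estimated correlation).

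The counts against the other 4 tissues were compared with 100 groupings of the 15 arrays into groups of the same sizes, the real one included. Groupings other than the real one mixed arrays of different tissues. A low share therefore excludes chance for the grouping as a whole, not for 1 tissue on its own. Only the real grouping gave as many features for epidermis (1 of 100, 990 against at most 86 in another), salivary gland (1, 1521 against 272), wing disc (1, 1669 against 317), midgut (1, 2506 against 11), central nervous system (1, 1866 against 1107) and the F test (1, 3750 against 655). The same held for features highest in epidermis (1; 241 against 0), salivary gland (1; 187 against 37), wing disc (1; 48 against 38) and midgut (1; 501 against 0). For features highest in central nervous system 2 of 100 groupings gave as many, and the other gave 400 against the real 100. In that grouping the 3 midgut arrays stood as the group, which points to the structure of the samples. For the number of lists called by camera at the preset correlation, 5 of 100 groupings gave at least the real 37, up to 39, so chance cannot be excluded for that number.

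The mean moderated statistic of each list was then compared across the same groupings, a test chosen after the number of lists was seen. The shares were not adjusted over the 85 tests. The other groupings mixed tissues, so a low share does not exclude chance for a list in 1 tissue. Of 85 tests of a list in a tissue, 42 had fewer than 5 groupings in 100 with a mean as large in size, and for the others chance was not excluded. Those others included 5 camera calls, of DNA replication genes in epidermis (14 of 100 groupings), digestive enzymes (10) and ribosomal protein genes (5) in salivary gland, V-ATPase genes in central nervous system (6) and ribosomal protein genes in wing disc (20; 1 of 29 higher; camera adjusted p = 0.048; adjusted p = 0.632 with an estimated correlation). For each tissue's own genes the mean was larger in the real grouping than in any other drawn, at 15.9 for salivary gland genes (highest other 2.81), 12.6 for midgut enzymes (2.98), 7.47 for muscle genes and 5.23 for cuticle genes in epidermis (2.67 and 1.97), 3.14 for disc genes in wing disc (1.28) and 2.35 for neuron and glia genes in central nervous system (2.01). The same held for secretory pathway genes in salivary gland at 5.62 (2.38), DNA replication genes in wing disc at 4.51 (2.38) and V-ATPase genes in wing disc at -3.63 (2.05 in size) and midgut at 3.37 (2.12). The 42 tests also included lists without a camera call in any tissue. These were heat shock genes in midgut (1 of 100 groupings), mitochondrial genes in epidermis (2), hemocyte genes in salivary gland (4) and testis and germline genes in wing disc (4).

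Pairs of tissues allow 10 splits of 6 arrays, too few for a share under 0.05. The real split gave the largest count in each pair (1 of 10), with 1072 features for epidermis against salivary gland (highest other 2), 1092 for epidermis against wing disc (1), 1689 for epidermis against midgut (1), 1484 for epidermis against central nervous system (0), 1797 for salivary gland against wing disc (10), 1532 for salivary gland against midgut (3), 1893 for salivary gland against central nervous system (9), 2487 for wing disc against midgut (0), 513 for wing disc against central nervous system (0) and 2611 for midgut against central nervous system (0). Comparisons with whole animal have no second group of samples, so they were not split.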
